A study of Bos taurus with 18 samples.

How the data were processed

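Poly(A) RNA was sequenced from the pituitary and the hypothalamus of 9 Angus cows, 3 each at 6, 18 and 30 months, which gave 18 libraries in 6 groups of 3. Per the labels, the cows had just been weaned at 6 months, were sexually mature at 18 months and had calved for the first time by 30 months, and none was in heat. The submitters' processing notes name HISAT2, StringTie, GATK and DESeq, with no role, version, genome build or annotation.

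The deposited gene table holds whole-number read counts for 27376 gene models, with no normalization. A second deposited table holds FPKM for the same gene models, which the authors computed as fragments scaled by gene model length and by the mapped fragments of the library; these values are close to the counts divided by gene model length and library total. The length of each gene model in bases is deposited with the counts, per the file headers, and is the same for all libraries. A deposited table of 992284 single-nucleotide polymorphism (SNP) sites gives, per the file headers, a called genotype for each library, the depth as a count of reads at the site, and the read counts of the reference and the alternative allele. A similar deposited table lists 112197 insertion or deletion sites. Chromosomes in these tables carry the names that NCBI gives to the UMD assembly of the cattle genome, no header names a build, and coordinates are printed as the table gives them.

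Columns were assigned to samples by the sample codes in the titles, and no column was left without a sample. Of the 27376 gene models, 21377 are named "gene" with a number and 5999 are new genes named by the authors. None of these identifiers (0 of 27376) matched the RefSeq gene table used here, so no gene symbol was given. For that reason the 39 gene lists fixed in advance, among them the markers of pituitary and brain cell types, were not run, and the rule for named genes, which asked for a gene symbol among the genes of largest change with adjusted p under 0.05 and for a set of hormone genes, named no gene. The single gene model printed was chosen after its values were seen.

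Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM factors, the expression filter of edgeR by group, and Benjamini-Hochberg adjusted p under 0.05. The 9 libraries of each tissue were fitted together with age as the group, which left 6 residual degrees of freedom, and each pair of ages was a contrast. An F test asked for any difference among the 3 ages. All 18 libraries, in 6 groups, served for the difference between tissues (the mean over ages, pituitary minus hypothalamus) and for the F test of whether the age effect differed between tissues. Age calls shared by the tissues were counted among the genes tested in both, with Fisher's exact test. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. The comparisons, tests, gene lists and most alternatives were chosen before the data were examined.

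The alternatives were RLE and upper-quartile factors, factors without the 20 most abundant genes, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 or on genes with an FPKM of at least 1 in 3 libraries, an added threshold of a 2-fold change, all 18 libraries in a single fit, only the 6 libraries of the ages compared, and each library left out in turn. Libraries of the same animal were found from the genotypes, and the tissue tests were repeated with animal as a block. Leaving out 2 animals from the blocked fits, and the paired sign-flip test of the variant measures, were added after seeing the data.

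Genotypes were compared between libraries at SNP sites read at least 20 times in both. For each library, 3 measures were taken over its non-reference SNP sites: their number, the percent heterozygous, and the percent with an A-to-G or T-to-C change. They were compared between tissues with a two-sided exact permutation test over all 48620 splits of 9 and 9 libraries. The alternatives kept only sites called in all 18 libraries, only sites in genes past the expression filter in both tissues, or only calls with a depth of at least 10. Reads like another animal were counted at autosomal sites read at least 20 times, where the other library of the animal and the other animal were homozygous for different alleles, and where that allele made up less than 20% of the reads. The depth and 20% limits were added after a first estimate over all sites had been seen to rest on a few sites. For each gene in each library, the reads at SNP sites in the 3′ untranslated region (UTR) were divided by those at coding sites, and the ratio was set against that of the other libraries. Gene model lengths were also taken without the library of each tissue with the highest such ratio, a choice made after these ratios were seen. Intervals for shares of reads are exact Clopper-Pearson 95% intervals, and they cover counting error only, since the reads carry no molecular identifiers.

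The fits were tested on simulated counts, drawn from the means, spread and library sizes of the real genes, with 200 changed genes per comparison at folds of 2, 4, 8 and 16. The share of these recovered is given with each comparison. Total counts per library ran from 28724861 to 38036840, and the median depth of called SNP sites was 4 or 5 reads. Other splits of the libraries were fitted the same way: all 10 for each pair of ages, and a seeded draw of 60 for the tests of any age and of 40 for the tests across tissues, fewer than 100 for the time they take. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the variant tables, and matplotlib 3.10.9 for the figures. The insertion and deletion sites were counted per library but not compared.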

Results

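Gene expression was measured by poly(A) RNA sequencing in the pituitary and the hypothalamus of Angus cows at 6 months (just weaned), 18 months (sexually mature) and 30 months (after the first calf), with 3 cows per age and both tissues from each cow. Each of the 6 groups held 3 libraries. Total gene counts ran from 28724861 in the 18-month pituitary replicate 1 to 38036840 in the 30-month pituitary replicate 1, and between 18830 and 21087 gene models had counts in a library. The tables do not pair the gene models with gene names, so hormone, receptor and cell type genes were not identified. Genes are described by their numbers, lengths and levels.

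Genotypes at SNP sites sorted the 18 libraries into 9 pairs. Within a pair, 99.4% to 99.7% of the genotypes were identical, against 50.2% to 66.4% between libraries of different pairs, over 25307 to 78857 sites. Each of the 9 pairs held 1 pituitary and 1 hypothalamus library of the same age and the same replicate number. No 2 count columns were identical (0 of 153 pairs of libraries), and the chi-square per degree of freedom was at least 49.3 between any 2 libraries and at most 772 within a group.

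The 18-month pituitary replicate 3 differed from the other libraries in how its reads lay along genes. Sites in 3′ UTRs took 39.2% of its SNP-site reads (median of the 18 libraries 23.3%) and introns 10.6% (median 20.3%). Within genes, the ratio of 3′ UTR to coding site reads had a median log2 value of 1.78 against the other libraries over 2398 genes, and the next highest library, the 18-month hypothalamus replicate 2, had 0.39 over 4382 genes. Across genes, which are not independent replicates, the correlation of log count with log gene model length was 0.334 in the 18-month pituitary replicate 3, 0.499 in the 18-month pituitary replicate 2, 0.483 in the 18-month hypothalamus replicate 2 and 0.489 in the 6-month hypothalamus replicate 3, against a median of 0.550 over the 18 libraries.

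**Figure D1:**
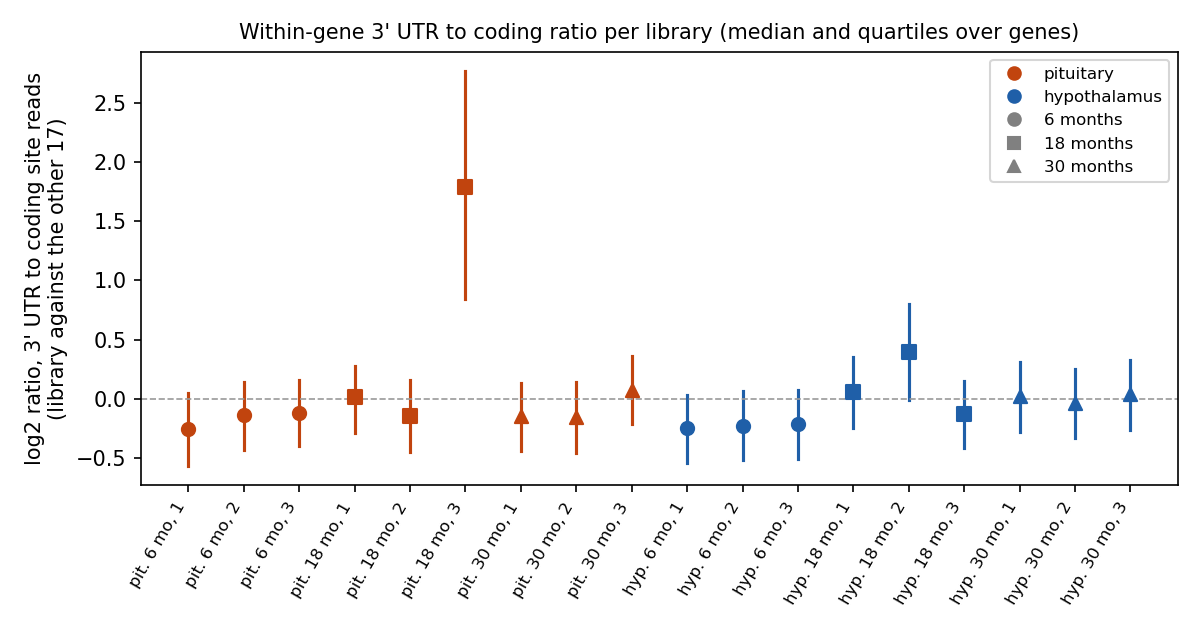
For each of the 18 libraries, the point gives the median over genes of the log2 ratio of 3′ UTR to coding site reads, relative to the other libraries, and the line its quartiles over genes; colours mark tissue and symbols age. The 18-month pituitary replicate 3 has a median of 1.78, and the next highest library has 0.39.

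Which genes differ between the pituitary and the hypothalamus was asked over all 18 libraries. Libraries of different tissues, as labelled, differed about as much as libraries of the same tissue did. Of the 100 most abundant gene models in each, 85 were the same. The median correlation of log2 CPM was 0.918 between libraries of the same tissue (72 pairs) and 0.913 between libraries of different tissues (81 pairs). The root mean square log2 difference had a median of 1.35 between both tissues of an animal (9 pairs), 1.32 between animals within a tissue (72 pairs) and 1.36 between animals across tissues (72 pairs). With edgeR, 0 of 19707 genes passed in the comparison of tissues; 1010 had an unadjusted p under 0.05, where 985.4 are expected by chance, and the smallest adjusted p was 0.175. DESeq2 called 87 genes, limma-voom 1, and limma-trend on FPKM 0. With animal as a block, edgeR called 0, with 932 genes at an unadjusted p under 0.05. In simulated counts for this comparison, 15 of 50 genes changed 2-fold and 45 of 50 changed 16-fold were recovered. Leaving out the 18-month pituitary replicate 2 gave 2 genes, and leaving out the 18-month hypothalamus replicate 3, the 30-month hypothalamus replicate 1 or the 30-month hypothalamus replicate 3 gave 1 each. The number at an unadjusted p under 0.05 was 1862 without the 18-month pituitary replicate 2, 1528 without the 6-month hypothalamus replicate 2 and 560 without the 30-month hypothalamus replicate 2.

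**Figure D2:**
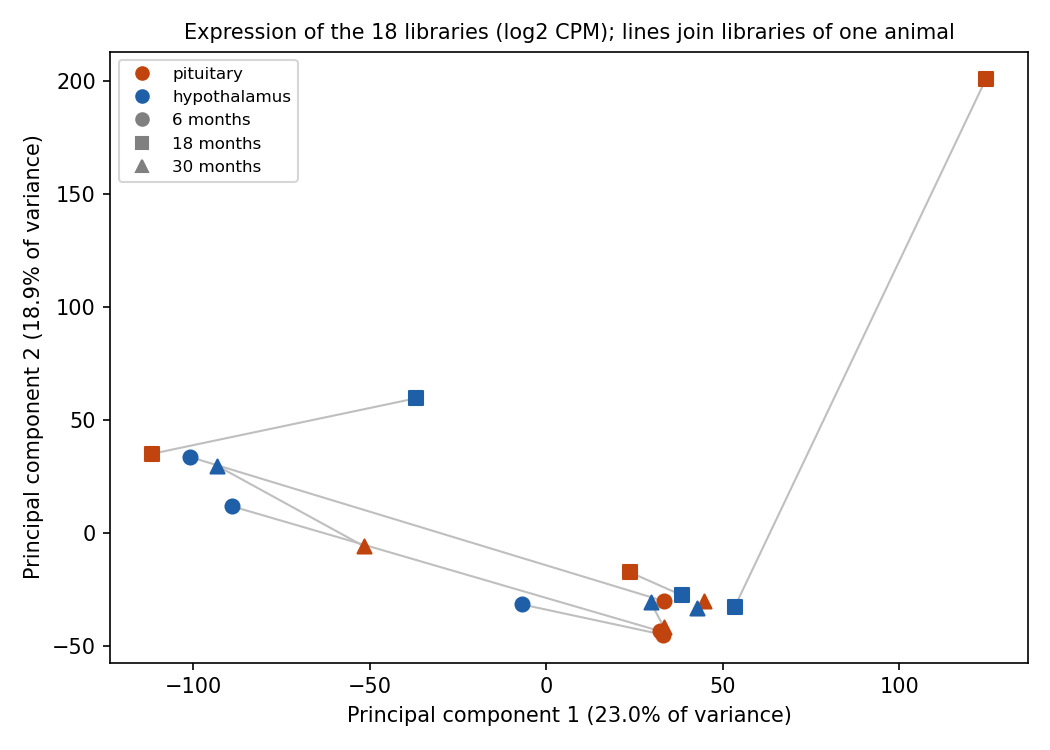
Principal components 1 (22.98% of the variance) and 2 (18.9%) of log2 CPM for the 18 libraries, with colour for tissue, symbol for age and a grey line joining the libraries of each animal. The 18-month pituitary replicate 3 lies at 200.7 on component 2, and the pituitary and hypothalamus libraries overlap on both components. On component 1 the 6-month pituitary libraries lie at 32.4, 33.2 and 33.3 and the 6-month hypothalamus ones at -89.0, -6.7 and -100.8. At 18 and at 30 months the tissues overlap on it.

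In the pituitary, the ages were compared to ask which genes change from weaning to maturity and to the first calf. A single gene model, gene5026, passed in the comparison of 18 with 6 months and of 30 with 6 months with edgeR. This gene model of 1523 bases lies on chromosome 4, where its 5 SNP sites, 4 nonsynonymous and 1 synonymous, span positions 94003181 to 94003649; it was chosen after its values were seen. Its pituitary level was 0.0455 ± 0.0541 CPM (SD, n = 3) at 6 months, 34.7 ± 13.4 CPM at 18 months and 41.95 ± 4.16 CPM at 30 months. The log2 fold change was 9.40 (SE 0.717, edgeR adjusted p = 0.00911) at 18 against 6 months and 9.61 (SE 0.721, adjusted p = 0.00798) at 30 against 6 months, higher in 3 of 3 libraries of each older group. Reads at SNP sites within gene5026, however, did not follow its counts: scaled to all site reads of the library (RPM) they were 93.2 ± 5.07 at 6 months, 89.7 ± 15.1 at 18 months and 90.7 ± 6.44 at 30 months (SD, n = 3). With 1 library left out, the adjusted p of gene5026 at 18 against 6 months was 0.198 without the 6-month replicate 3 and 0.0600, 0.0569 and 0.0581 without the 30-month replicates 1, 2 and 3, and over all alternatives it ran from 1.68e-32 to 0.198. The log2 fold change itself was 4.12 and 7.21 with limma-trend on FPKM with pseudocounts of 1 and 0.1. At 30 against 6 months its adjusted p ran from 6.66e-34 to 1 over the alternatives. The log2 fold change of gene5026 there ran from 9.11 to 11.01 with a library left out and from 4.45 to 9.71 over the other settings. In the hypothalamus its log2 fold change at 18 against 6 months was 1.74 (SE 2.50, adjusted p = 0.828 with edgeR), and the difference in its age effect between tissues had an edgeR adjusted p of 0.795.

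**Figure D3:**
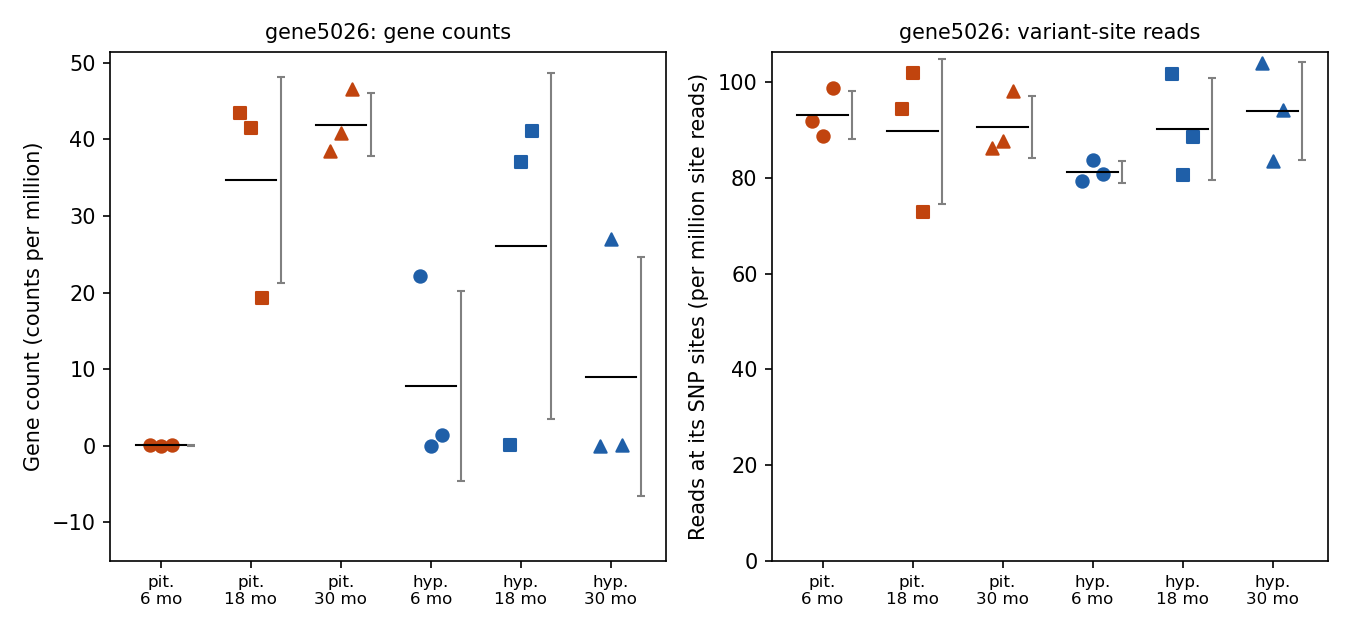
gene5026 in each library by tissue and age: left, its gene count in CPM; right, reads at its 5 SNP sites in RPM of all site reads. Points are libraries, black lines group means and grey bars the SD of 3 libraries; pituitary counts at 6 months are 0.0455 CPM on average while site reads are 93.2 RPM.

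At 18 against 6 months in the pituitary, 1 of 18555 genes passed, and it was higher at 18 months. An unadjusted p under 0.05 was found for 2392 genes, where 927.8 are expected by chance. Another split of the same libraries gave 1172, so an excess over 927.8 alone does not show a shift with age. Of the 2392 genes, 1568 were higher and 824 lower at 18 months. The higher ones had a median gene model length of 2480 bases and the lower ones 9422 bases, against 4760 bases for all genes tested. Without the 18-month replicate 3, which had the raised 3′ UTR share, 1911 were higher and 1093 lower, with median lengths of 4343 and 8267 bases, and 1 gene passed. The number at an unadjusted p under 0.05 was 1039, 1368 and 1032 without the 6-month replicates 1, 2 and 3, and 4047 without the 18-month replicate 1. DESeq2 called 330 genes in the same comparison, 219 higher and 111 lower. Leaving out the 18-month replicate 1 gave 40 genes with edgeR, the 18-month replicate 2 gave 3, and the 6-month replicate 3 or any of the 30-month libraries gave 0. In simulated counts, 0 of 50 genes changed 2-fold, 8 of 50 changed 4-fold and 34 of 50 changed 16-fold were recovered.

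At 30 against 18 months in the pituitary, edgeR called 0 of 18555 genes. An unadjusted p under 0.05 was found for 1381, of which 503 were higher at 30 months (median length 8396 bases) and 878 lower (2326 bases). Without the 18-month replicate 3 the median lengths were 7744 and 4604 bases. The number at an unadjusted p under 0.05 was 3096 and 2365 without the 18-month replicates 1 and 2, and 660 and 846 without the 30-month replicates 1 and 3; it was 515 with only the 6 libraries of these ages and 2374 with all 18 libraries in a single fit, where 927.8 are expected by chance in the fit of 9. DESeq2 called 119 genes and the limma fits 0, and edgeR called 7 without the 18-month replicate 1. At 30 against 6 months 1 gene passed with edgeR, 353 genes had an unadjusted p under 0.05, where 927.8 are expected by chance, and DESeq2 called 27. The 353 became 203 and 213 without the 6-month replicates 1 and 3, 570 and 815 without the 18-month replicates 2 and 3, 230 without the 30-month replicate 2, 1141 with only the 6 libraries of these ages and 1280 with limma-voom and sample quality weights. The edgeR count at 30 against 6 months was 2 without the 18-month replicate 2, and 0 without the 6-month replicate 3 or any of the 30-month libraries. Any difference among the ages was called for 1 gene with edgeR, gene5026 at an adjusted p of 0.0271, and for 212 with DESeq2. At an unadjusted p under 0.05 there were 1410, where 927.8 are expected by chance, and these became 692, 831 and 702 without the 6-month replicates 1, 2 and 3 and 2800 without the 18-month replicate 1. With all 18 libraries in a single fit the number was 2596. The edgeR count for any difference was 5 without the 18-month replicate 1, 1 without the 18-month replicate 3 and 0 without any other library. In simulated counts, 34 of 50 genes changed 16-fold were recovered at 30 against 18 months, 30 of 50 at 30 against 6 months and 34 of 50 for any difference among the ages.

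In the hypothalamus, no gene model passed with edgeR between any of the ages (0 of 18763 tested in each comparison). At 18 against 6 months, 1652 genes had an unadjusted p under 0.05, against 938.2 expected by chance; 735 were higher at 18 months (median length 4049 bases) and 917 lower (7151 bases), the median over all tested being 4720 bases. The within-gene log2 ratio of 3′ UTR to coding reads was 0.05, 0.39 and -0.13 in the 18-month replicates 1, 2 and 3, each above the -0.25, -0.23 and -0.21 of the 6-month replicates. The 30-month replicates, at 0.03, -0.03 and 0.04, also lay above all of the 6-month ones. Where reads lay along genes thus cannot be told apart from age between 6 months and the older groups. Without the 18-month replicate 2 the lengths lay the other way, with a median of 6702.5 bases for the 752 genes higher at 18 months and 5019 bases for the 1205 lower. The number of 1652 became 858 without the 6-month replicate 1 and 1032 without the 18-month replicate 1. At 30 against 18 months the number was 389, at 30 against 6 months 658, and for any difference among the ages 838. The 658 became 1460 without the 6-month replicate 2 and 362, 2298 and 375 without the 30-month replicates 1, 2 and 3. The 838 became 498 and 1354 without the 6-month replicates 1 and 2, and 1838 without the 30-month replicate 2. With limma-voom and sample quality weights, the numbers at an unadjusted p under 0.05 were 4298 at 18 against 6 months, 1006 at 30 against 18, 2864 at 30 against 6 and 3012 for any difference. DESeq2 called 93, 13 and 44 genes in these pairs of ages and 57 for any difference, and limma-voom and limma-trend called 0 in each. At 30 against 6 months, leaving out the 30-month replicate 2 gave 1 gene with edgeR. In simulated counts, 39, 39 and 40 of 50 genes changed 16-fold were recovered in the comparisons of 18 with 6, 30 with 18 and 30 with 6 months, and 35 of 50 for any difference. In the same order, 21, 22, 21 and 20 of 50 genes changed 4-fold were recovered, and 0, 2, 3 and 0 of 50 changed 2-fold. The biological coefficient of variation was 51.6% in the hypothalamus and 58.6% in the pituitary.

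Whether age acted differently in the tissues was tested over all 18 libraries. The edgeR test called 0 of 19707 genes, 1189 had an unadjusted p under 0.05, DESeq2 called 43, and the limma fits called 0. The 1189 became 2449 and 2060 without the 18-month pituitary replicates 1 and 3, 742, 1860 and 668 without the 18-month hypothalamus replicates 1, 2 and 3, 768 without the 6-month hypothalamus replicate 1 and 3142 with limma-voom and sample quality weights. The edgeR count was 10 without the 18-month pituitary replicate 1 and 2 without the 30-month hypothalamus replicate 3, and 0 with animal as a block. In simulated counts, with the change placed in the 18-month pituitary alone, 29 of 50 genes changed 16-fold were recovered. The recovery was 10 of 50 for genes changed 4-fold and 0 of 50 for 2-fold. Genes called in both tissues in the same direction numbered 0 with edgeR for each of the 3 pairs of ages, since no gene passed in the hypothalamus. With genes at an unadjusted p under 0.01 in both tissues, 6 overlaps were tested, and the tissues share animals, so their p are descriptive. At 18 against 6 months, 1 gene was shared among the higher (1.73 expected for independent lists, Fisher's exact p = 1) and 4 among the lower (1.23 expected, Fisher's exact p = 0.0353, adjusted 0.0728). At 30 against 18 months, 1 was shared among the higher (0.131 expected, Fisher's exact p = 0.123) and 0 among the lower (0.139 expected). At 30 against 6 months, 3 were shared among the higher (0.0647 expected, Fisher's exact p = 3.59e-05, adjusted 0.000215) and 1 among the lower (0.037 expected, Fisher's exact p = 0.0364, adjusted 0.0728). Among genes called by DESeq2 in both tissues, with p likewise descriptive, the overlaps were 1 higher (0.198 expected, Fisher's exact p adjusted over 6 overlaps 0.217) and 3 lower (0.301 expected, adjusted 0.0103) at 18 against 6 months. They were 1 higher (0.0201 expected, adjusted 0.0298) and 0 lower (0.00952 expected) at 30 against 18 months, and 2 higher (0.0123 expected, adjusted 0.000401) and 1 lower (0.00833 expected, adjusted 0.0166) at 30 against 6 months.

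The SNP sites were compared between tissues as a measure of RNA sequence. Pituitary libraries had 191498 ± 49162 non-reference SNP sites and hypothalamus libraries 187759 ± 35234 (SD, n = 9 each; exact permutation p = 0.863, two-sided). Heterozygous sites made up 40.93% ± 2.19 and 41.03% ± 2.36 of these (exact permutation p = 0.922). A-to-G plus T-to-C changes, the kind that RNA editing by deamination of adenosine gives, made up 38.05% ± 0.211 and 37.87% ± 0.252 (exact permutation p = 0.125, adjusted over the 3 measures 0.374), and the pituitary was higher in 7 of 9 animals. That difference of 0.177 percentage points had an exact permutation p of 0.0494 without the 6-month pituitary replicate 2 and 0.0367 without the 18-month hypothalamus replicate 1. It was 0.0462 points with only sites called in all 18 libraries and 0.0394 points at a depth of at least 10.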

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

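Of the tests given here, those of reads from other animals, of library size and of age for gene5026 were chosen only after the results were seen, as were the limits of 20 reads and of 100 counts they use; the within-gene 3′ UTR test was fixed before its result but after the library's raised overall 3′ UTR share had been seen. Age was first to be judged by how many libraries were out of place for it, which left it open at 4 of 18 (1 six-month library with counts and 3 older ones without), and the ratio of site reads was then used in its place.

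Libraries labelled pituitary and hypothalamus did not separate by expression, although the 2 tissues are known to make different hormones and simulated 16-fold differences were recovered for 45 of 50 genes. An exchange of labels within some animals would leave the 9 within-animal expression differences along a common axis, but their median absolute cosine was 0.0565 (0.00161 to 0.478 over 36 pairs of animals), which argues against it. For the libraries as a set, a small mixture of reads from other animals, absent from the other library of the animal, is argued against as well. The highest percent of reads like another animal had a median of 0.0539 over the libraries. The 6-month hypothalamus replicate 1 is excepted. Its highest percent was 0.841, against at most 0.0802 in any other library, so a small mixture in it is not argued against. Sites were counted only below the limit on the allele's share of reads, and where the other library of the animal was homozygous for a different allele. A larger mixture, or a mixture shared by both libraries of an animal, could drop out of this count and was not tested. A mixture of both tissues of the same animal, or samples taken from the same tissue, would leave the genotypes alike and was not tested. A likeness of the sampled tissues themselves remains open too, as untested. In libraries labelled pituitary the most abundant gene model took 0.284% to 1.89% of the counts. The mean was 0.847%, against 1.18% in libraries labelled hypothalamus. Whether the libraries labelled pituitary hold pituitary RNA was not tested.

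The 18-month pituitary replicate 3 lay far from the other 8 pituitary libraries in 6 measures. It had the fewest genes with counts (18830), the fewest non-reference SNP sites (75571), the lowest share of site reads in introns (10.6%), the highest in 3′ UTRs (39.2%), a within-gene log2 ratio of 3′ UTR to coding reads of 1.78, and a TMM factor of 0.847. A library with fewer counted reads is argued against by its total count, 1.06 times the median. The total does not show how many distinct molecules were sequenced, and a shortage of these was not tested. This library also had the fewest SNP sites read at least 10 times, 54178 against a median of 116982. Reads of another animal are argued against by a highest share of 0.0802%. That holds only for a mixture below the 20% limit and absent from the other library of the cow. Reads concentrated near the 3′ end, as partly degraded RNA selected by its poly(A) tail gives, may account for it, but the within-gene ratio of 1.78 is itself among these measures and was tested after the 39.2% had been seen, so it shows where the reads lay and leaves open whether that gave the other measures. The other library of the same cow, the 18-month hypothalamus replicate 3, had a within-gene log2 ratio of -0.13. It had 20486 genes with counts and 20.2% of its site reads in introns, so the departure was not shared by both libraries of this cow. The animal is a single cow, so no biological explanation was tested.

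For gene5026, 8 libraries had at most 42 counts and 10 had 653 to 1464. Reads at its SNP sites numbered 401 to 721 in the first 8 libraries and 243 to 572 in the other 10, and in RPM of all site reads the median of the first was 1.07 times that of the other libraries. Counting of the reads under another gene model in some libraries may therefore account for the pattern, but no other gene model is shown here to hold these reads. A change in transcription with age is argued against by the pituitary site reads in RPM, which at 18 months were 0.963 times those at 6 months.

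Of 30 sets of 9 libraries searched for a library far from the rest, 1.5 are expected to hold such a library by chance, and 12 were found, 6 of them the measures of the 18-month pituitary replicate 3 above. The 10 most abundant genes took 6.98% of the counts in the 18-month pituitary replicate 2. In the 30-month hypothalamus replicate 3, new genes took 5.30% of the counts and the most abundant gene 3.11%. The 18-month hypothalamus replicate 2 had a within-gene log2 ratio of 3′ UTR to coding reads of 0.39. The TMM factor of the 6-month hypothalamus replicate 3 was 0.913.

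In the 6-month hypothalamus replicate 1, reads of the less frequent allele made up 4.28% of the reads at mitochondrial SNP sites (exact 95% interval 4.07 to 4.51), in data outside the comparisons, and the next library had 0.471%. Of these reads, 95.2% lay at the 129 sites where the mitochondrial lineages of the 9 animals differ. At autosomal sites 0.841% of its reads (exact 95% interval 0.789 to 0.895) were like animal 6, the 18-month replicate 3, against 0.489% for the next animal and at most 0.0802% in any other library.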

How the results depend on the processing

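Fits leaving out 2 animals, and the paired tests of the variant measures, were chosen after the data were seen; the other alternatives were planned. The lists of genes and their alternatives were not run, for want of gene names. DESeq2 gave more calls than edgeR throughout. In the pituitary it gave 330 genes at 18 against 6 months, 119 at 30 against 18, 27 at 30 against 6 and 212 for any age difference; in the hypothalamus 93, 13, 44 and 57; and 87 between tissues and 43 for a differing age effect. Limma-voom gave 3 pituitary genes at 30 against 6 months, 2 for any age difference and 1 between tissues. Limma-trend with a pseudocount of 1, with 0.1 and on genes of FPKM 1 or more gave 3, 4 and 3 pituitary genes at 18 against 6 months, 2, 2 and 2 at 30 against 6, and 2, 3 and 3 for any age difference. A fit of all 18 libraries gave 0 in these 3 pituitary comparisons, and a fit of the 6 libraries alone 0 at 18 against 6 months and 4 at 30 against 6. The cause was not tested. Other normalizations, count filters and the fold threshold kept the edgeR counts within 1.5 times.

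With each library left out in turn, the pituitary counts ran from 0 to 40 at 18 against 6 months (40 without the 18-month replicate 1, 3 without the 18-month replicate 2, 0 without the 6-month replicate 3 or any 30-month library), 0 to 7 at 30 against 18, 0 to 2 at 30 against 6 and 0 to 5 for any age difference. The hypothalamus counts ran from 0 to 0 at 18 against 6 and at 30 against 18 months, 0 to 1 at 30 against 6 and 0 to 0 for any age difference. The counts ran from 0 to 2 between tissues and from 0 to 10 for a differing age effect. The blocked fits gave 0 in each case, also without the 2 animals. The log2 fold change of gene5026 at 18 against 6 months ran from 8.90 to 10.80 with a library left out and from 4.12 (limma-trend, pseudocount 1) to 9.70 over the other settings.

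Genes shared between tissues, 0 with edgeR, numbered with DESeq2 and at an unadjusted p under 0.01 respectively 1 and 1 (higher) and 3 and 4 (lower) at 18 against 6 months, 1 and 1 (higher) at 30 against 18, and 2 and 3 (higher) and 1 and 1 (lower) at 30 against 6. With DESeq2 the adjusted Fisher's exact p passed and with the unadjusted lists it did not for the lower at 18 against 6 months (0.0103 against 0.0728), the higher at 30 against 18 (0.0298 against 0.184) and the lower at 30 against 6 (0.0166 against 0.0728).

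The difference in non-reference SNP sites, 3739 more in the pituitary, became -299 with sites called in all 18 libraries and -18.6 at a depth of 10 or more, and ran from -3440 to 18230 with a library left out; by library it reversed to -3223, -886, -2220, -3440 and -210. The heterozygous difference of -0.105 percentage points was -0.734 with sites called in all 18 libraries, ran from -0.660 to 0.441 with a library left out, and reversed to 0.441, 0.161, 0.257, 0.257 and 0.0570 without 1 library. The A-to-G plus T-to-C difference of 0.177 fell to 0.0462 with sites called in all 18 libraries and 0.0394 at a depth of 10 or more, and ran from 0.130 to 0.233 with a library left out. No exact permutation p of the first 2 measures passed. In simulated counts the edgeR fits of age in the pituitary recovered 0 of 50 genes changed 2-fold, so changes of that size are below what those fits could show. The fits of age in the hypothalamus recovered 0 of 50 at 18 against 6 months, 2 at 30 against 18 and 3 at 30 against 6. They recovered 0 of 50 for any age difference. The test of a differing age effect recovered 0 of 50, and the comparison of tissues recovered 15 of 50.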

Other observations

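The counts of called genes over other splits were planned, and the counts of splits by unadjusted p, the tests on the mitochondrial lineages and on genes nearly absent from a library were chosen after the data were seen, with limits of 5 and 500 counts set from them.

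Mitochondrial SNP sites divided the 9 animals into lineages of 5 and 4. Between lineages, animals differed at 122 to 141 sites, against at most 18 and 9 sites within them, and libraries of the same animal differed at 0. The lineage of 5 held 2 of the 6-month, 1 of the 18-month and 2 of the 30-month cows.

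Some gene models, gene5026 among them, had at most 5 counts in 1 library of an animal and at least 500 in the other library. There were 259 such cases, 120 of them in new genes, with 4 to 53 in a library. In 101 of them the fuller library had at least 20 site reads, and in 49 of these (48.5%) the emptier library had at least 50% as many site reads.

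The libraries of each pair of ages make only 10 splits of 3 and 3, too few for a share under 0.05. All counts of splits that reach the real number, here and below, include the real split itself. At 18 against 6 months in the pituitary, 2 of 10 splits called as many genes as the real 1, and the highest other gave 1; by genes at an unadjusted p under 0.05 the real split had 2392 and the highest other 1172. At 30 against 6 months 2 of 10 gave as many as the real 1 (highest other 1). Where the real count was 0, every split gives as many, so the counts of 10 of 10 decide nothing: the highest others were 1 for the pituitary at 30 against 18 months, and 1, 2 and 755 for the hypothalamus at 18 against 6, 30 against 18 and 30 against 6 months. By genes at an unadjusted p under 0.05, 5 of 10 splits, the real split included, had as many as the real split in that pituitary comparison, and 2, 5 and 4 of 10 in the hypothalamus.

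For any age difference in the pituitary, 13 of 60 splits called as many genes as the real 1 (highest other 2), so chance could not be excluded. The other real counts were 0, which 60 of 60 splits for any age difference in the hypothalamus and 40 of 40 in each comparison across tissues reach by construction, so these decide nothing. Their highest others were 1546 in the hypothalamus, 1086 between tissues, 1 for a differing age effect and 0 with labels exchanged within animals. By genes at an unadjusted p under 0.05, as many as the real number were found in 7 of 60 splits for any age difference in the pituitary (real 1410, highest other 2580), in 13 of 60 for the hypothalamus, and in 15, 6 and 9 of 40 between tissues, for a differing age effect and with labels exchanged within animals.

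The 755 genes came from the split that set the 6-month replicates 1 and 3 and the 30-month replicate 2 of the hypothalamus against the 6-month replicate 2 and the 30-month replicates 1 and 3. The split with 1546 genes kept those 3 libraries (the 6-month replicates 1 and 3 and the 30-month replicate 2) as a group and put the 18-month replicates 1 and 3 with the 30-month replicate 3. The split with 1086 genes followed the tissues at 6 months and mixed them at 18 and 30 months. Counts so far above the real ones point to a structure of the libraries other than the real grouping. The first principal component of the hypothalamus libraries, 38.4% of the variance, placed the 6-month replicates 1 and 3 and the 30-month replicate 2 at 69.0, 108.2 and 82.4, the 18-month replicate 2 at 39.3 and the other 5 below 0.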
